A study of Mus musculus with 10 samples.

How the data were processed

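RNA was sequenced from embryoid bodies of a mouse iHA-Etv2 line, with 2 libraries in each of 5 groups: untreated and doxycycline-treated at day 2, untreated and doxycycline-treated at day 2.5, and Flk1-positive doxycycline-treated at day 2.5. The values are raw counts per gene as deposited by the authors. The tools named are TopHat, HTSeq and DESeq2, with mm10 as the genome build, per the submitters' processing notes, which give no versions and do not say which tool did what. The gene annotation, the strand setting of the counting and the handling of reads that map to several places are not given in the sources used here. Reads of overlapping genes, of antisense partners and of near-identical copies therefore cannot be told apart from these counts.

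The deposited table has 23429 entries. Of these, 92 are spike-in sequences with 0 counts in every library, which were left out, and 4811 genes had 0 counts in every library. Total counts were 23358858 and 18666747 in untreated day 2 replicates 1 and 2, 21255952 and 21134667 with doxycycline at day 2, and 23326111 and 24710072 in untreated day 2.5 samples. They were 36068329 and 34650432 with doxycycline at day 2.5 and 23042226 and 18074070 in Flk1-positive samples. A count of 0 in a library allows a level of up to 3 counts, which is 0.0824 to 0.164 CPM of TMM-scaled library size depending on the library. No 2 libraries of a group were identical, and replicate pairs differed by more than sampling noise, with a chi-square per gene between 3.4 and 33.9.

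Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 14548, and libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 10 libraries with robust estimation, leaving 5 residual degrees of freedom and a common biological coefficient of variation of 0.1. There were 7 comparisons, each with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. They were doxycycline against none at each day, Flk1-positive against doxycycline and against untreated samples of day 2.5, day 2.5 against day 2 with and without doxycycline, and the interaction of doxycycline and day. CPM values use TMM-scaled library sizes, and log2 fold changes are given ± the standard error taken from the quasi-likelihood F statistic. Where a group held 0 counts of a gene, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts it is a ratio with an exact 95% counting interval.

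Groups, comparisons, tests, gene lists and most alternatives were fixed before the data were examined. Etv2 and Kdr were named in every comparison. For the first 3 comparisons the 8 rising and 8 falling genes with the largest log2 fold change were named, and 5 and 5 for the others, among genes past the threshold with a mean of at least 5 CPM in the higher group, no overlap between the groups and a named symbol; overlap was not considered for the interaction. Up to 4 members per gene list with the smallest adjusted p were also open to naming. The 23 lists covered endothelial, haematopoietic, naive pluripotency, formative epiblast, primitive streak and mesendoderm, cardiac and lateral mesoderm, paraxial mesoderm, neuroectoderm, definitive and extraembryonic endoderm, fibroblast, smooth muscle and leukocyte genes. They also covered the ETS family, the Notch pathway, the SWI/SNF complex, the cell cycle, p53 targets, immediate early and dissociation genes, the integrated stress response, hypoxia and glycolysis, the study's qPCR genes, and the mitochondrially encoded genes. Of 396 list genes, 383 were in the table, 3 of them under an older symbol. None of the 13 mitochondrially encoded genes was in the table, so 22 lists were tested. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison.

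The procedure was tested on simulated data with 200 changed genes, drawn at each gene's mean over all 10 libraries and at the real library sizes. Each gene had 1 dispersion for all groups. For doxycycline at day 2 (14239 genes in the fit), edgeR recovered 25.0%, 77.3% and 89.1% of genes changed 1.5-, 2- and 4-fold, and 8.15% of its calls were false. For doxycycline at day 2.5 (14225 genes) the shares were 52.3%, 79.1% and 89.4% with 4.58% false, and for Flk1-positive against doxycycline samples (14236 genes) 52.2%, 81.8% and 89.2% with 8.12% false. The false share was above the 5% aimed at in the first and the last of these. Real doxycycline day 2 libraries differed more from each other (chi-square per gene 33.9) than the pairs of other groups (3.4 to 10), which the simulation did not reproduce. The simulated shares for that comparison therefore do not cover this excess. In a simulation of doxycycline at day 2.5 with all 31 endothelial genes raised 2-fold (14250 genes), camera called that list (adjusted p = 1.77e-62) and none of 20 other lists. The study's qPCR list, which shares genes with the endothelial list, was left out of that count. Genes were drawn independently of each other, so this simulation could not show false list calls that arise from correlation between genes. A simulated trend on gene length had a rank correlation of 0.62 over all simulated genes, those without a known length being set to the mean log2 length. After the trend removal it was -0.012 over the 14377 genes with a known length and GC content. The simulated trend was of a form that the removal fits, so this checks only that the step works as built.

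Gene lengths, GC content and coordinates came from the GENCODE annotation of GRCm38, the assembly that mm10 also denotes. Of 23337 symbols, 20915 matched 1 gene by symbol and 1912 more through a RefSeq synonym. The alternatives were RLE, upper quartile and library size scaling, no filter, a filter at 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, a test against a fold of 1.5 (glmTreat), fits of the compared groups alone, the replicate number as a block, and leaving out each library in turn. With 1 library of a group left out, the remaining one is assumed to vary like the other groups. Thinning to the smallest total, removing trends on gene length and GC content, and leaving out small RNA genes were added after the data were seen.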

Results

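The series measured messenger RNA in mouse embryoid bodies, which are aggregates of differentiating embryonic stem cells. The cells belong to an iHA-Etv2 line, in which doxycycline switches on an HA-tagged copy of Etv2, an ETS transcription factor needed for the formation of blood and endothelial cells. The 10 libraries fall into 5 groups of 2, namely untreated and doxycycline-treated embryoid bodies at day 2 and at day 2.5, and Flk1-positive doxycycline-treated samples at day 2.5. Flk1 is the receptor encoded by Kdr, a surface marker of the precursors of blood and endothelium. The other 8 libraries are labelled as not Flk1-positive, and the labels do not say whether those cells were unsorted or sorted as negative. Total counts per library ran from 18074070 to 36068329, and 14548 genes were tested. The labels do not say that the 2 replicates of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

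The first principal component of log2 CPM held 60.2% of the variance and the second 13.7%. On the first component the Flk1-positive libraries stood at 96.8 and 99.2, the doxycycline day 2.5 libraries at 34.1 and 33.5, and the 6 other libraries between -53.9 and -31.3. Etv2 lies on chromosome 7 at 30633616 to 30635852 and Kdr on chromosome 5 at 75932827 to 75978458, both on the minus strand of GRCm38. Reads from the induced copy of Etv2 and from the gene at its own locus cannot be told apart in these counts.

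**Figure D1:**
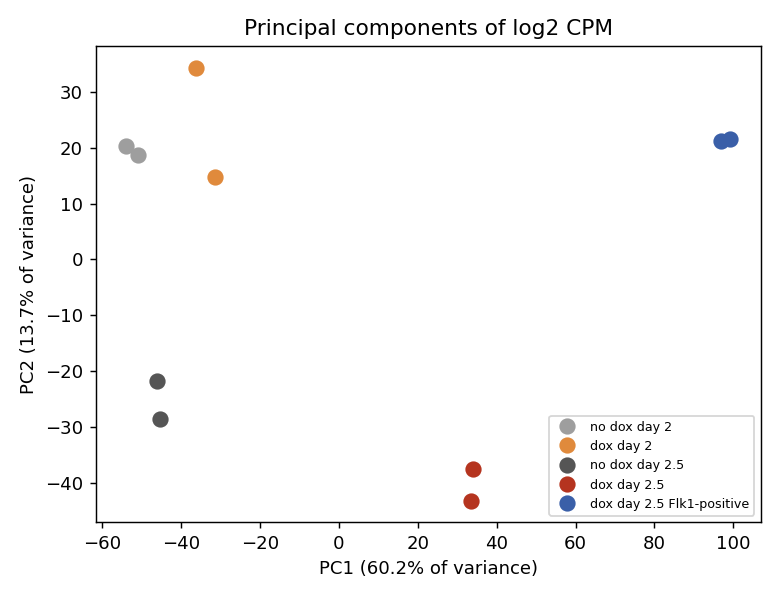
Principal components of log2 CPM, with 1 point per library and 1 colour per group. The horizontal axis holds 60.2% of the variance and the vertical axis 13.7%, and the Flk1-positive libraries lie at 96.8 and 99.2 on the horizontal axis.

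The first comparison asked what doxycycline changed at day 2. Etv2 rose from 16.9 ± 1.62 to 455 ± 73.9 CPM (SD, n = 2; log2 fold change 4.75 ± 0.13 SE; edgeR with Benjamini-Hochberg adjustment, adjusted p = 6.84e-12), and Kdr rose from 28.8 ± 0.48 to 125 ± 36.2 CPM (log2 2.12 ± 0.15, adjusted p = 4.22e-07). Tal1 also rose, from 2.68 ± 0.61 to 48.8 ± 2.47 CPM, as did its partner Lmo2 from 8.49 ± 0.36 to 55.4 ± 0.98 CPM and the endothelial factor Sox18 from 1.12 ± 0.19 to 22.1 ± 5.10 CPM. The pluripotency factor Nanog fell from 216 ± 5.06 to 87.0 ± 1.61 CPM and the signalling gene Nodal from 175 ± 3.45 to 87.8 ± 10.7 CPM.

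The largest rises among named genes also included Pcdh12, an endothelial protocadherin (log2 5.09 ± 0.29), Lax1 (4.04 ± 0.43), Rhoj (3.61 ± 0.22), Sox9 (3.57 ± 0.33) and Arhgap31 (3.56 ± 0.17), with edgeR adjusted p from 3.30e-08 to 2.56e-05 for Pcdh12 and Lax1. The largest falls were Ccdc160 (-1.86 ± 0.28), Dact1 (-1.55 ± 0.17), Slitrk2 (-1.5 ± 0.36), Sp8 (-1.46 ± 0.16), Rgma (-1.46 ± 0.23), Dll1 (-1.37 ± 0.35), Apln (-1.36 ± 0.15) and Nanog (-1.31 ± 0.12). The exons of Dact1 overlap another annotated gene over 34.9% of their length and those of Dll1 over 20.5%. The calls of Slitrk2 and Dll1 were lost without untreated day 2 replicate 1 (adjusted p = 0.122 and 0.505), that of Slitrk2 also without replicate 2 (0.167), and that of Dll1 without doxycycline day 2 replicate 1 (0.0529) or either untreated day 2.5 library (0.0561 and 0.0584). The Dll1 call was also lost with only the compared groups fitted (0.215), with limma-voom (0.0562) and with counts thinned to the smallest total (0.0575).

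Of 31 measured endothelial genes, 11 rose and 2 fell (17 and 2 adjusted over the list alone), and the list was higher than the other genes (camera, adjusted p = 1.38e-06, and adjusted p = 0.0447 with an estimated correlation). Flt4, a receptor of lymphatic and early vascular endothelium, rose by a log2 of 1.78 ± 0.13, while Apln fell. Of 21 primitive streak and mesendoderm genes, 1 rose and 8 fell (1 and 13 adjusted over the list alone; camera, adjusted p = 1.18e-05, but adjusted p = 0.242 with an estimated correlation). Sp5 and Fst fell by 0.88 and 0.72 on the log2 scale, and Mixl1, a streak homeobox gene, was the member that rose (0.82 ± 0.09). Of 18 hypoxia and glycolysis genes, 5 fell and none rose (2 rose and 7 fell adjusted over the list alone; camera, adjusted p = 5.34e-04, but adjusted p = 0.183 with an estimated correlation). Slc2a1 changed by -0.82 ± 0.10 and Hk2 by -0.63 ± 0.08 on the log2 scale. Of 13 genes on the study's own qPCR panel, 7 rose (7 adjusted over the list alone; camera, adjusted p = 1.39e-06, but adjusted p = 0.0762 with an estimated correlation); the study chose this list, so it is not independent evidence. The counts in these lists moved with single libraries and with the fit. Without untreated day 2 replicate 1 or 2, 7 endothelial genes rose (6 with only the compared groups fitted). Without replicate 1, 5 primitive streak genes fell, against 4 in the fit of the compared groups and 13 with gene length and GC trends removed. Falling hypoxia and glycolysis genes numbered 2 without untreated day 2 replicate 2 or in the fit of the compared groups, 9 without doxycycline day 2 replicate 1 and 8 with trends removed.

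No call was made by camera for the other lists. Of 19 haematopoietic genes 4 rose and 1 fell (4 and 2 adjusted over the list alone; adjusted p = 0.547). Hhex changed by 1.62 ± 0.12 on the log2 scale. Of 18 ETS family genes 3 rose (4 and 2 lower adjusted over the list alone; adjusted p = 0.363), including Elk3 at 2.54 ± 0.12 and Fev, which had 158 counts with doxycycline and 2 without, a ratio of 78.6 (95% counting interval 21.4 to 654). Of 13 Notch pathway genes 2 rose and 4 fell (4 and 6 adjusted over the list alone; adjusted p = 0.981). Nrarp changed by 1.74 ± 0.11 on the log2 scale, with exons that overlap another gene over 79.4% of their length, and Hes1 by -0.63 ± 0.10, a call lost with only the compared groups fitted (adjusted p = 0.0710). Of 16 immediate early and dissociation genes 6 rose and 1 fell (7 and 2 adjusted over the list alone; adjusted p = 0.202). Fos changed by 2.07 ± 0.24 and Egr1 by -1.25 ± 0.16 on the log2 scale. Of 22 naive pluripotency genes 2 fell (1 higher and 4 lower adjusted over the list alone; adjusted p = 0.432), and of 14 formative epiblast genes 2 rose and 3 fell (4 and 5 adjusted over the list alone; adjusted p = 0.981). None of 19 SWI/SNF complex, 20 cell cycle, 15 p53 target, 17 cardiac and lateral mesoderm or 9 smooth muscle genes was called over all genes or adjusted over the list alone (camera, adjusted p = 0.981 for all but smooth muscle, at 0.369). Without doxycycline day 2 replicate 1 or 2, however, up to 3 genes of a list among these were called higher and up to 5 lower, and DESeq2 called 1 cardiac and lateral mesoderm gene higher. The count of 4 falling Notch genes was 2 without either untreated day 2 library and 0 with only the compared groups fitted, and that of 2 rising ones was 1 in each of these and 5 without doxycycline day 2 replicate 1. The count of 6 rising immediate early and dissociation genes was 2 or 1 without untreated day 2 replicate 1 or 2, 3 without doxycycline day 2.5 replicate 1 and 1 in the fit of the compared groups. The count of 3 rising ETS genes was 6 without doxycycline day 2 replicate 1, where 6 naive pluripotency genes fell (4 with trends removed). The counts of 2 rising and 3 falling formative epiblast genes were 0 and 1 without either untreated day 2 library and 0 and 0 in the fit of the compared groups; 4 rose without doxycycline day 2 replicate 1, and 5 fell without replicate 2 or with trends removed.

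In all, 453 genes rose and 227 fell at day 2 at an adjusted p under 0.05, and these counts moved with single libraries. Without untreated day 2 replicate 1 or 2, 188 or 196 genes rose and 58 or 59 fell; without doxycycline day 2 replicate 1 or 2, 1035 or 1022 rose and 733 or 1275 fell; and without doxycycline day 2.5 replicate 2, 150 fell. The 2 doxycycline day 2 libraries differed more than any other pair, with a chi-square per gene of 33.9 against 3.4 to 10. Their difference was correlated across genes with exon length (rank correlation 0.57) and GC content (-0.39). Within the Flk1-positive pair the difference was also correlated with GC content (-0.5), and less with exon length (0.16).

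**Figure D2:**
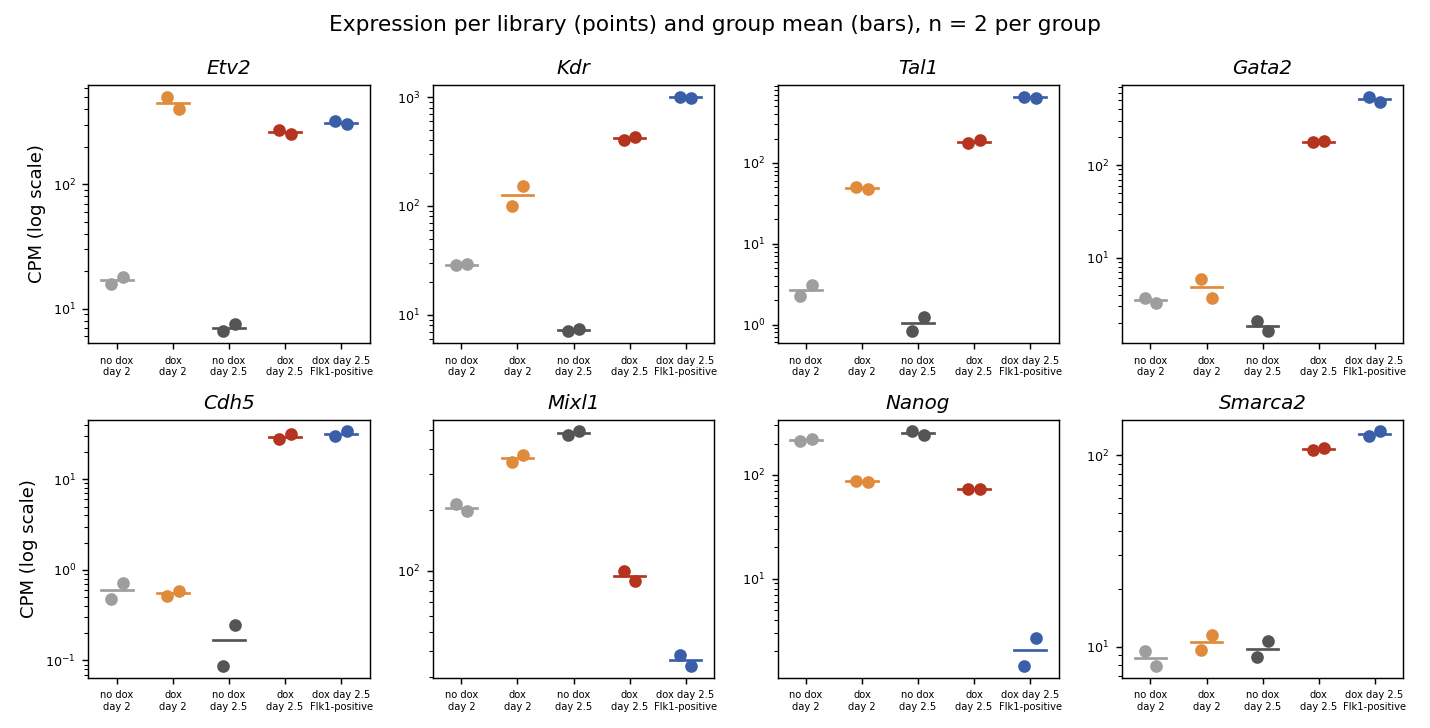
Expression in CPM on a log axis for 8 genes, with 1 point per library and a bar at the mean of each group (n = 2). Etv2 stood at 7.04 CPM in untreated and 263 CPM in doxycycline-treated samples at day 2.5, and Kdr at 7.23, 419 and 997 CPM in untreated, doxycycline and Flk1-positive samples of that day.

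The second comparison asked what doxycycline changed at day 2.5. Etv2 rose from 7.04 ± 0.66 to 263 ± 11.5 CPM (SD, n = 2; log2 5.22 ± 0.14; edgeR, adjusted p = 5.38e-13) and Kdr from 7.23 ± 0.26 to 419 ± 20.1 CPM (log2 5.85 ± 0.18, adjusted p = 3.16e-12). Among genes that rose, Lmo2 stood at 308 ± 2.98 against 6.69 ± 0.08 CPM, Tal1 at 184 ± 9.65 against 1.04 ± 0.29 CPM, Gata2 at 180 ± 5.79 against 1.85 ± 0.33 CPM and the endothelial cadherin Cdh5 at 29.4 ± 2.52 against 0.17 ± 0.11 CPM. Eomes, a regulator active in the primitive streak, fell to 335 ± 2.20 from 1330 ± 177 CPM and Mixl1 to 94.5 ± 7.12 from 479 ± 14.5 CPM.

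The largest rises were in genes almost without counts in untreated samples. Tal2, a relative of Tal1, had 725 counts against 0, at least 160-fold higher, and Ctse had 365 against 0, at least 80.7-fold higher, both against a floor of 3 counts over the group. Myct1 had 918 counts against 1, a ratio of 609 (95% counting interval 109 to 24100), Fev 859 against 1, a ratio of 570 (102 to 22500), and Dbx1 419 against 1, a ratio of 278 (49.6 to 11000). Fli1, an ETS factor of blood and endothelium, rose by a log2 of 9.25 ± 0.28, Sox7 by 7.74 ± 0.34 and Rcsd1 by 7.64 ± 0.33 (edgeR, adjusted p = 2.35e-12 for Fli1). The largest falls were Fgf17 (-3.64 ± 0.24), Apln (-3.49 ± 0.16), Wnt11 (-3.36 ± 0.31), Frzb (-3.31 ± 0.22), Mesp1 (-3.26 ± 0.29), Etv4 (-3.16 ± 0.11), Wnt8a (-2.76 ± 0.13) and Wnt5b (-2.71 ± 0.19). Intervals and floors cover counting error only.

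Of 31 endothelial genes, 26 rose and 1 fell (29 and 1 adjusted over the list alone; camera, adjusted p = 1.20e-18, and adjusted p = 0.00386 with an estimated correlation). Sox18 changed by 7.57 ± 0.22 and Rhoj by 6.88 ± 0.26 on the log2 scale. Of 19 haematopoietic genes, 14 rose and 2 fell (14 and 2 adjusted over the list alone; camera, adjusted p = 3.05e-07, but adjusted p = 0.0549 with an estimated correlation). Hhex changed by 3.66 ± 0.11 on the log2 scale. Of 21 primitive streak and mesendoderm genes, 19 fell (19 adjusted over the list alone; camera, adjusted p = 5.81e-14, but adjusted p = 0.0532 with an estimated correlation). Fst changed by -2.42 ± 0.12 and Lhx1 by -2.37 ± 0.14 on the log2 scale. Of 14 formative epiblast genes, 3 rose and 10 fell (3 and 10 adjusted over the list alone; camera, adjusted p = 0.00169, but adjusted p = 0.182 with an estimated correlation). Etv5 changed by -1.88 ± 0.08 and Zic2 by -1.29 ± 0.09 on the log2 scale. Of 22 naive pluripotency genes, 7 rose and 7 fell (8 and 7 adjusted over the list alone; camera, adjusted p = 0.876). Tdgf1 changed by -1.84 ± 0.09, Nanog by -1.78 ± 0.12 and Tbx3 by 1.5 ± 0.15 on the log2 scale.

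Of 18 ETS family genes, 7 rose and 2 fell (7 and 2 adjusted over the list alone; camera, adjusted p = 0.0372, but adjusted p = 0.439 with an estimated correlation). Elk3 changed by 3.95 ± 0.12 and Etv1 by -2.20 ± 0.13 on the log2 scale. Of 13 Notch pathway genes, 6 rose and 2 fell (6 and 2 adjusted over the list alone; camera, adjusted p = 0.0304, but adjusted p = 0.247 with an estimated correlation). Nrarp changed by 1.49 ± 0.10 and Notch1 by 1.43 ± 0.11 on the log2 scale. Of 5 leukocyte genes, 4 rose (4 adjusted over the list alone; camera, adjusted p = 0.00473, but adjusted p = 0.0963 with an estimated correlation), with Coro1a, an actin regulator, at 1.82 ± 0.17 and Laptm5 at 2.13 ± 0.27. Of 9 neuroectoderm genes, 3 rose (3 adjusted over the list alone; camera, adjusted p = 0.0372, but adjusted p = 0.182 with an estimated correlation), namely Tubb3 at 1.09 ± 0.12, Sox3 at 0.58 ± 0.17 and Pax6 at 1.40 ± 0.46. The calls of Sox3 and Pax6 were lost without any 1 of the 4 libraries compared (adjusted p from 0.0532 to 0.156 and from 0.0507 to 0.184), and that of Pax6 with counts thinned to the smallest total (0.0692). Of 15 integrated stress response genes, 1 rose and 7 fell (1 and 8 adjusted over the list alone; camera, adjusted p = 0.0380, but adjusted p = 0.480 with an estimated correlation). Mthfd2 changed by -1.20 ± 0.11 and Psat1 by -0.66 ± 0.09 on the log2 scale. Of 13 genes on the study's qPCR panel, 9 rose (9, and 1 lower, adjusted over the list alone; camera, adjusted p = 4.69e-07, but adjusted p = 0.0532 with an estimated correlation), which is not independent evidence. Some list calls at day 2.5 depended on single libraries. That of the neuroectoderm list was lost without either doxycycline day 2 library (camera, adjusted p = 0.0684 and 0.0685), doxycycline day 2.5 replicate 1 or 2 (0.217 and 0.0579) or untreated day 2.5 replicate 1 (0.255). That of the ETS list was lost without replicate 2 of the doxycycline or the untreated day 2.5 samples (0.0550 and 0.0878), and that of the integrated stress response list without either doxycycline day 2 library (0.0584 and 0.0581) or untreated day 2.5 replicate 1 (0.108). The count of 3 rising neuroectoderm genes was 1 without any 1 of the 4 libraries compared, and the count of 7 falling integrated stress response genes was 4 or 3 without doxycycline day 2.5 replicate 1 or 2 and 3 without untreated day 2.5 replicate 1. With trends on gene length and GC content removed, a setting chosen after seeing the data, the calls of the Notch (camera, adjusted p = 0.145), ETS (0.0763), neuroectoderm (0.0509) and integrated stress response (0.0502) lists were lost.

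Smarca2, a catalytic subunit of the SWI/SNF remodelling complex, rose from 9.72 ± 1.32 to 108 ± 2.05 CPM (edgeR, log2 3.47 ± 0.13, adjusted p = 2.75e-11). The other catalytic subunit, Smarca4, which was added after its values were seen, stood at 686 ± 15.1 against 668 ± 10.8 CPM (log2 0.04 ± 0.09, adjusted p = 0.784). Of 19 SWI/SNF genes, 3 rose (3 adjusted over the list alone; camera, adjusted p = 0.876), namely Smarca2, Arid1b and Smarcc2. Only Smarca2 remained without doxycycline day 2.5 replicate 1 or 2 or untreated day 2.5 replicate 1, with adjusted p = 0.0678, 0.0876 and 0.0628 for Arid1b and 0.141, 0.0600 and 0.153 for Smarcc2. Without untreated day 2.5 replicate 2 the Arid1b call was lost (0.0507), and 4 genes of this list fell without either doxycycline day 2 library. The cell type lists that follow were not called by camera. Of 17 cardiac and lateral mesoderm genes 5 rose and 5 fell (5 and 5 adjusted over the list alone; adjusted p = 0.788). Tbx20 changed by 3.32 ± 0.19 and Snai1 by -1.13 ± 0.11 on the log2 scale. Of 11 definitive endoderm genes 3 rose and 4 fell (5 and 5 adjusted over the list alone; adjusted p = 0.876). Trh changed by -2.21 ± 0.10 and Sox9 by 4.71 ± 0.25 on the log2 scale. Of 14 extraembryonic endoderm genes 4 rose (4 adjusted over the list alone; adjusted p = 0.489). Apoe changed by 1.63 ± 0.11 on the log2 scale. Of 11 paraxial mesoderm genes 2 rose and 5 fell (2 and 5 adjusted over the list alone; adjusted p = 0.398), and of 12 fibroblast genes 2 rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p = 0.876). The count of 5 rising cardiac and lateral mesoderm genes was 3 without untreated day 2.5 replicate 2. The count of 5 falling paraxial mesoderm genes was 2 or 1 without doxycycline day 2.5 replicate 1 or 2, 3 or 1 without untreated day 2.5 replicate 1 or 2, and 3 with counts thinned to the smallest total. In all, 2349 genes rose and 2001 fell at day 2.5. The number of falling genes was 1032 without doxycycline day 2.5 replicate 2, and 1200 or 1333 without untreated day 2.5 replicate 1 or 2. No doxycycline-treated sample without the induced gene was analysed here, so effects of the drug itself are part of each doxycycline comparison.

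**Figure D3:**
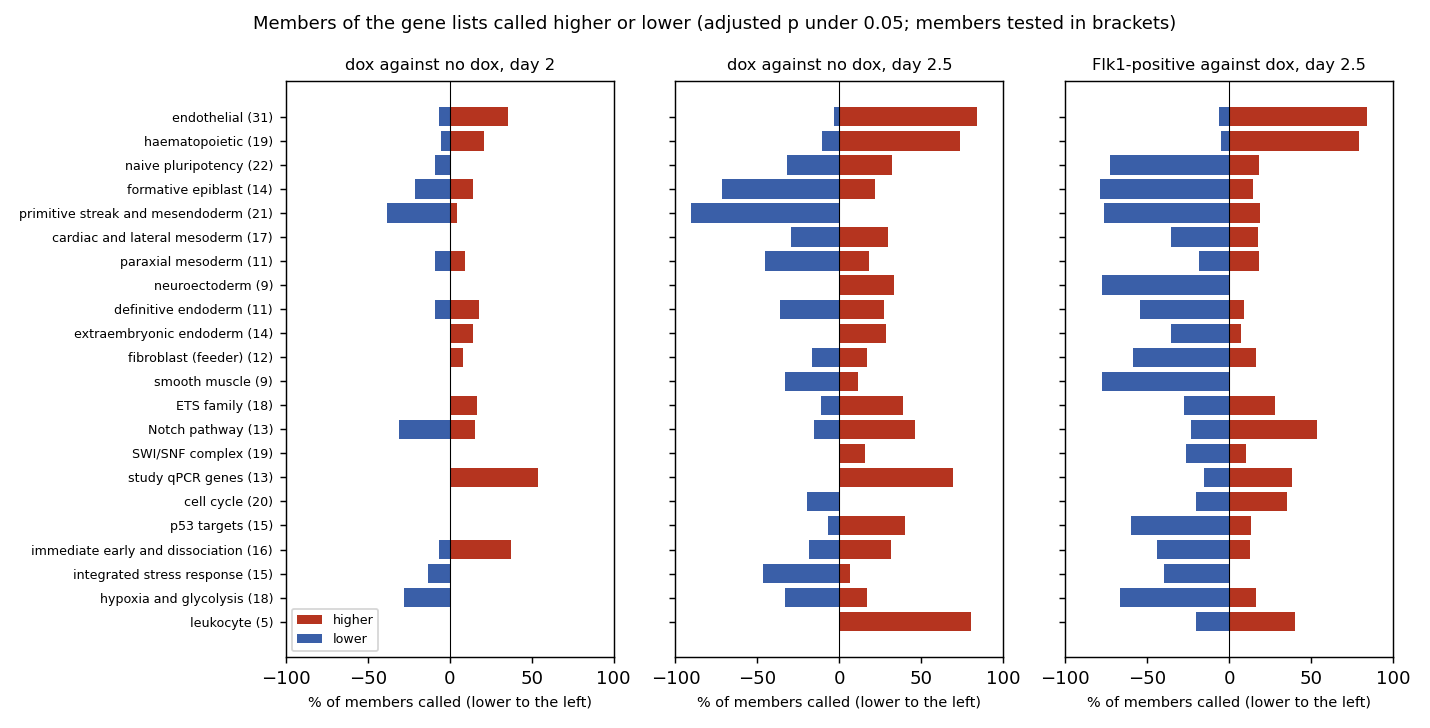
Share of the measured members of each gene list that were called higher (to the right) or lower (to the left) at an edgeR adjusted p under 0.05, in percent, for 3 comparisons, with the number of members tested in brackets. Of 31 endothelial genes, 11 were higher with doxycycline at day 2, 26 at day 2.5 and 26 in Flk1-positive samples.

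The third comparison set Flk1-positive samples against the other doxycycline-treated samples of day 2.5. Kdr, which encodes the marker that names these samples, stood at 997 ± 15.3 against 419 ± 20.1 CPM (SD, n = 2; log2 1.25 ± 0.14; edgeR, adjusted p = 5.76e-06). Etv2 stood at 313 ± 14.0 against 263 ± 11.5 CPM (log2 0.25 ± 0.11, adjusted p = 0.0762), a difference that did not pass the test. It passed without either doxycycline day 2 library (adjusted p = 0.00313 and 0.00308), with only the compared groups fitted (0.00225), with gene length and GC trends removed (0.00204), with scaling by library size alone (0.0360) and without a filter (0.0494). Among genes that were higher, Tal1 stood at 651 ± 15.1 against 184 ± 9.65 CPM, Gata2 at 514 ± 49.5 against 180 ± 5.79 CPM and the endothelial receptor Tek at 74.2 ± 1.58 against 26.1 ± 3.06 CPM. Among genes that were lower, Nanog stood at 2.07 ± 0.89 against 73.4 ± 0.08 CPM and Nodal at 3.79 ± 0.19 against 47.2 ± 0.31 CPM.

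The largest rises were Stab1, a scavenger receptor of endothelium (log2 4.34 ± 0.50), Tie1, an endothelial receptor kinase (3.37 ± 0.29), Kcne3 (3.17 ± 0.22), Fam65b (3.07 ± 0.41), the megakaryocyte integrin Itga2b (2.99 ± 0.28), Tnfrsf25 (2.92 ± 0.51) and 2 genes known by clone-like symbols, D17H6S56E-3 (3.41 ± 0.29) and D7Ertd143e (3.37 ± 0.36). The largest falls were Klf2 (-5.73 ± 0.36), Wnt8a (-5.51 ± 0.24), Lefty1 (-5.50 ± 0.38), Nanog (-5.19 ± 0.17), Trim67 (-5.11 ± 0.25), Eras (-4.95 ± 0.41), Gdf3 (-4.76 ± 0.29) and Lefty2 (-4.64 ± 0.26), with edgeR adjusted p from 1.85e-11 for Nanog to 3.36e-07 for Eras.

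Of 31 endothelial genes, 26 were higher and 2 lower (26 and 4 adjusted over the list alone; camera, adjusted p = 5.05e-07, and adjusted p = 0.0387 with an estimated correlation). Aplnr changed by 2.24 ± 0.11 and Esam by 2.78 ± 0.14 on the log2 scale. Pecam1, given here outside the naming rule, was among the lower genes, at 5.40 ± 0.16 against 8.35 ± 1.83 CPM. Its call was lost with limma-voom (adjusted p = 0.0635) and with library size scaling (edgeR, adjusted p = 0.0634). It was also lost without doxycycline day 2.5 replicate 2 (log2 -0.39), Flk1-positive replicate 1 or 2 (log2 -0.59 and -0.66) or untreated day 2 replicate 2 (log2 -0.63). Of 19 haematopoietic genes, 15 were higher and 1 lower (15 and 1 adjusted over the list alone; camera, adjusted p = 1.83e-05, but adjusted p = 0.0927 with an estimated correlation). Zfpm1 changed by 1.52 ± 0.11 and Lmo2 by 0.94 ± 0.08 on the log2 scale. Of 22 naive pluripotency genes, 4 were higher and 16 lower (4 and 16 adjusted over the list alone; camera, adjusted p = 9.11e-05, but adjusted p = 0.0610 with an estimated correlation). Tdgf1 changed by -3.06 ± 0.10 and Sox2 by -2.74 ± 0.13 on the log2 scale. Pou5f1, also outside the naming rule, was not called, at 827 ± 43.3 against 725 ± 16.6 CPM. It was called higher with only the compared groups fitted (log2 0.19, edgeR adjusted p = 0.0143) and with gene length and GC trends removed (log2 0.25, adjusted p = 0.0133). Pou5f1 was also called higher without either doxycycline day 2 library (log2 0.19 for both), although these are not part of the comparison. Of 14 formative epiblast genes, 2 were higher and 11 lower (2 and 11 adjusted over the list alone; camera, adjusted p = 6.55e-05, but adjusted p = 0.103 with an estimated correlation). Etv5 changed by -3.11 ± 0.09 on the log2 scale. Of 21 primitive streak and mesendoderm genes, 4 were higher and 16 lower (4 and 16 adjusted over the list alone; camera, adjusted p = 1.21e-04, but adjusted p = 0.170 with an estimated correlation). Fst changed by -2.52 ± 0.13 and Sp5 by -2.75 ± 0.15 on the log2 scale. The count of 4 higher naive pluripotency genes was 2 without replicate 1 of either group.

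Of 9 neuroectoderm genes, 7 were lower (7 adjusted over the list alone; camera, adjusted p = 4.07e-04, but adjusted p = 0.0773 with an estimated correlation). Sox3 changed by -1.99 ± 0.19 on the log2 scale. Without replicate 1 of either group, 4 neuroectoderm genes were lower. Of 9 smooth muscle genes, 7 were lower (7 adjusted over the list alone; camera, adjusted p = 0.00199, but adjusted p = 0.232 with an estimated correlation). Cnn1 changed by -1.35 ± 0.12 on the log2 scale. Of 11 definitive endoderm genes, 1 was higher and 6 lower (1 and 6 adjusted over the list alone; camera, adjusted p = 0.0465, but adjusted p = 0.170 with an estimated correlation). Trh changed by -3.22 ± 0.11 on the log2 scale. Of 14 extraembryonic endoderm genes, 1 was higher and 5 lower (1 and 5 adjusted over the list alone; camera, adjusted p = 0.0482, but adjusted p = 0.170 with an estimated correlation). Rhox5 changed by -2.0 ± 0.17 on the log2 scale. Of 12 fibroblast genes, 2 were higher and 7 lower (2 and 7 adjusted over the list alone; camera, adjusted p = 0.0482, but adjusted p = 0.170 with an estimated correlation). Thy1 changed by -0.98 ± 0.16 and Fn1, an abundant matrix gene, by 0.80 ± 0.12 on the log2 scale. Of 5 leukocyte genes 2 were higher and 1 lower (2 and 1 adjusted over the list alone; camera, adjusted p = 0.772). Of 17 cardiac and lateral mesoderm genes 3 were higher and 6 lower (3 and 6 adjusted over the list alone; camera, adjusted p = 0.246), and of 11 paraxial mesoderm genes 2 were higher and 2 lower (2 and 2 adjusted over the list alone; camera, adjusted p = 0.505). The calls of the definitive endoderm, extraembryonic endoderm and fibroblast lists lay near the threshold. Each was lost without doxycycline day 2 replicate 1 (camera, adjusted p = 0.0513, 0.0513 and 0.0915) or replicate 2 (0.0508, 0.0508 and 0.0904), Flk1-positive replicate 2 (0.0617, 0.106 and 0.0617) or untreated day 2.5 replicate 2 (0.0506, 0.0564 and 0.0506). The extraembryonic endoderm and fibroblast calls were also lost without doxycycline day 2.5 replicate 1 (0.0557 for both) or untreated day 2 replicate 2 (0.0537 and 0.0519), and the extraembryonic endoderm call without untreated day 2 replicate 1 (0.0579). With gene length and GC trends removed, the definitive and extraembryonic endoderm calls were lost (0.0628 and 0.0615).

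Of 18 hypoxia and glycolysis genes, 3 were higher and 12 lower (3 and 12 adjusted over the list alone; camera, adjusted p = 4.07e-04, but adjusted p = 0.103 with an estimated correlation). Of 15 p53 target genes, 2 were higher and 9 lower (3 and 9 adjusted over the list alone; camera, adjusted p = 0.0482, but adjusted p = 0.170 with an estimated correlation). Perp changed by -1.77 ± 0.20 on the log2 scale. The p53 call was lost without any library except doxycycline day 2.5 replicate 2, Flk1-positive replicate 1 and untreated day 2.5 replicate 1 (camera, adjusted p from 0.0506 to 0.0617), and with gene length and GC trends removed (0.0615). Of 18 ETS family genes 5 were higher and 5 lower (5 and 5 adjusted over the list alone; camera, adjusted p = 0.768). Fli1 changed by 1.54 ± 0.14 and Etv4 by -1.83 ± 0.14 on the log2 scale. The count of 5 higher ETS genes was 2 or 3 without doxycycline day 2.5 replicate 1 or 2 and 3 or 2 without Flk1-positive replicate 1 or 2, and that of 5 lower ones was 3 without doxycycline day 2.5 replicate 1. Of 13 Notch pathway genes 7 were higher and 3 lower (7 and 3 adjusted over the list alone; camera, adjusted p = 0.102). Hey1 changed by 1.27 ± 0.13 and Notch3 by -1.07 ± 0.10 on the log2 scale. Of 16 immediate early and dissociation genes 2 were higher and 7 lower (2 and 8 adjusted over the list alone; camera, adjusted p = 0.0564). Of 87 small nucleolar RNA and microRNA genes 62 were higher and 1 lower, and together they held 605 and 589 CPM in the Flk1-positive libraries against 243 and 220 CPM. They held 321 and 300 CPM in the untreated day 2.5 libraries, 539 and 524 CPM in those of day 2, and 621 and 384 CPM with doxycycline at day 2. In all, 2982 genes were higher and 3104 lower in Flk1-positive samples. The number of higher genes was 1909 without doxycycline day 2.5 replicate 2. Both Flk1-positive libraries and no others carry that label, so any difference in the handling of these samples is part of the comparison.

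Flk1-positive samples were also set against untreated samples of day 2.5. Kdr stood at 997 ± 15.3 against 7.23 ± 0.26 CPM (SD, n = 2; edgeR, log2 7.11 ± 0.18, adjusted p = 1.94e-13) and Etv2 at 313 ± 14.0 against 7.04 ± 0.66 CPM (log2 5.48 ± 0.14, adjusted p = 1.12e-13). Among the largest rises, Tal2 was at least 370-fold higher, the interleukin receptor gene Il9r at least 237-fold, Ctse at least 149-fold and Mpo, which encodes myeloperoxidase, at least 121-fold, each against 0 counts in untreated samples. Fli1 rose by a log2 of 10.79 ± 0.27. The largest falls were Wnt8a (-8.27 ± 0.22), Fgf17 (-7.54 ± 0.37) and Trim67 (-7.41 ± 0.23), with Cdx1 at 1 count against 268, a ratio of 245 (95% counting interval 43.6 to 9720), and Cabp7 at 2 against 487, a ratio of 223 (61.3 to 1840). In all, 4167 genes were higher and 3873 lower.

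Among the 31 endothelial genes 28 were higher and 1 lower in this comparison (28 and 1 adjusted over the list alone; camera, adjusted p = 5.75e-14, and adjusted p = 0.00777 with an estimated correlation). Of 19 haematopoietic genes 16 were higher and 1 lower (16 and 1 adjusted over the list alone; camera, adjusted p = 7.66e-07, but adjusted p = 0.0998 with an estimated correlation). Tal1 changed by 9.28 ± 0.17 on the log2 scale. Of 21 primitive streak and mesendoderm genes 18 were lower (18 adjusted over the list alone; camera, adjusted p = 2.67e-10, but adjusted p = 0.0998 with an estimated correlation). Of 22 naive pluripotency genes 4 were higher and 12 lower (5 and 12 adjusted over the list alone; camera, adjusted p = 0.0125, but adjusted p = 0.135 with an estimated correlation). Nanog changed by -6.97 ± 0.17 on the log2 scale. Of 14 formative epiblast genes 2 were higher and 11 lower (2 and 11 adjusted over the list alone; camera, adjusted p = 2.28e-04, but adjusted p = 0.135 with an estimated correlation). Of 9 smooth muscle genes 7 were lower (7 adjusted over the list alone; camera, adjusted p = 0.00655, but adjusted p = 0.295 with an estimated correlation), and 4 were lower without untreated day 2.5 replicate 2. Of 15 integrated stress response genes 8 were lower (8 adjusted over the list alone; camera, adjusted p = 0.00655, but adjusted p = 0.310 with an estimated correlation). Of 18 hypoxia and glycolysis genes 3 were higher and 11 lower (3 and 11 adjusted over the list alone; camera, adjusted p = 0.00393, but adjusted p = 0.142 with an estimated correlation). Of the 13 genes on the study's qPCR panel, which the study chose, 8 were higher and 1 lower (8 and 1 adjusted over the list alone; camera, adjusted p = 0.00157, but adjusted p = 0.135 with an estimated correlation).

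Between day 2 and day 2.5 without doxycycline, Etv2 fell from 16.9 ± 1.62 to 7.04 ± 0.66 CPM (SD, n = 2; edgeR, log2 -1.26 ± 0.14, adjusted p = 7.28e-05) and Kdr from 28.8 ± 0.48 to 7.23 ± 0.26 CPM (log2 -1.99 ± 0.17, adjusted p = 7.99e-06). T rose to 835 ± 61.2 from 390 ± 2.42 CPM and Eomes to 1330 ± 177 from 556 ± 10.1 CPM. The endoderm regulator Foxa2 rose by a log2 of 2.30 ± 0.27, the largest rise, followed by Foxp2 (1.76 ± 0.46), Otx1 (1.63 ± 0.34), Oprd1 (1.61 ± 0.39) and Hrc (1.59 ± 0.35). Slc28a1 (-2.75 ± 0.36), Kcnh3 (-2.47 ± 0.43), Morc1 (-2.38 ± 0.21), Rps15a-ps4 (-2.34 ± 0.32) and Hsd17b14 (-2.30 ± 0.29) fell most; Rps15a-ps4 is a pseudogene symbol and its reads may belong to its parent gene. The calls of Foxp2 and Oprd1 were lost without any 1 of the 4 libraries compared (adjusted p from 0.0597 to 0.139 and from 0.0551 to 0.111), that of Otx1 without replicate 2 of either group (0.0704 and 0.0544) and that of Hrc without untreated day 2 replicate 1 (0.0756) or untreated day 2.5 replicate 2 (0.0583).

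In this comparison 1342 genes rose and 1494 fell. Of 22 naive pluripotency genes 2 rose and 14 fell (2 and 16 adjusted over the list alone; camera, adjusted p = 5.47e-06, and adjusted p = 0.0322 with an estimated correlation). Zfp42 changed by -1.44 ± 0.15 on the log2 scale. Of 15 p53 target genes 11 fell (11 adjusted over the list alone; camera, adjusted p = 3.16e-06, and adjusted p = 0.0322 with an estimated correlation). Plk2 changed by -1.66 ± 0.10 on the log2 scale. Among 21 primitive streak and mesendoderm genes 9 rose (9, and 2 lower, adjusted over the list alone; camera, adjusted p = 3.08e-04, but adjusted p = 0.247 with an estimated correlation). Among 31 endothelial genes 4 rose and 9 fell (4 and 11 adjusted over the list alone; camera, adjusted p = 0.0150, but adjusted p = 0.136 with an estimated correlation). Of 14 extraembryonic endoderm genes 1 rose and 4 fell (2 and 7 adjusted over the list alone; camera, adjusted p = 0.0488, but adjusted p = 0.204 with an estimated correlation). Of the 13 genes that the study chose for qPCR 6 fell (6 adjusted over the list alone; camera, adjusted p = 6.74e-04, but adjusted p = 0.136 with an estimated correlation). The count of 11 falling p53 target genes was 7 without untreated day 2 replicate 1 and 5 without untreated day 2.5 replicate 2. The count of 4 rising endothelial genes was 1 without any 1 of the 4 libraries compared, and that of 9 falling ones was 5 without untreated day 2 replicate 2 or with limma-voom. The count of 4 falling extraembryonic endoderm genes was 2 without untreated day 2 replicate 1 or either untreated day 2.5 library. The endothelial call was lost without untreated day 2.5 replicate 1 (camera, adjusted p = 0.0560). The extraembryonic endoderm call was lost without that library (0.0596), either doxycycline day 2 library (0.0899 and 0.0901), untreated day 2 replicate 1 (0.0915) or either Flk1-positive library (0.0559 and 0.0558), and with gene length and GC trends removed (0.101). The counts depended on single libraries: 358 genes rose and 322 fell without untreated day 2.5 replicate 2, 960 fell without its replicate 1, 414 or 406 rose and 481 or 460 fell without untreated day 2 replicate 1 or 2, and 2266 or 2261 rose and 2536 or 2532 fell without doxycycline day 2 replicate 1 or 2.

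Between day 2 and day 2.5 with doxycycline, Etv2 fell from 455 ± 73.9 to 263 ± 11.5 CPM (SD, n = 2; edgeR, log2 -0.79 ± 0.11, adjusted p = 4.06e-05), while Kdr rose from 125 ± 36.2 to 419 ± 20.1 CPM (log2 1.74 ± 0.14, adjusted p = 2.89e-07). Fli1 rose by a log2 of 8.73 ± 0.27, Cdh5 by 5.72 ± 0.25 and Gata2 by 5.21 ± 0.16. Myct1 was at least 179-fold higher than in day 2 samples, where it had 0 counts, Erg had 819 counts against 1, a ratio of 480 (95% counting interval 85.9 to 19000), and Tal2 725 against 2, a ratio of 213 (58.6 to 1760). Tgm3 (-4.32 ± 0.37), Etv4 (-3.31 ± 0.11), Nefl (-2.88 ± 0.12), Kcnh3 (-2.72 ± 0.43) and Fzd9 (-2.56 ± 0.31) fell most, and the exons of Nefl overlap those of Nefm over 32.8% of their length. In all, 3337 genes rose and 3361 fell. With doxycycline, 26 of 31 endothelial genes rose and 2 fell (26 and 2 adjusted over the list alone; camera, adjusted p = 7.97e-10, and adjusted p = 0.0179 with an estimated correlation). Of 19 haematopoietic genes 15 rose and 1 fell (15 and 1 adjusted over the list alone; camera, adjusted p = 2.05e-06, but adjusted p = 0.134 with an estimated correlation). Of 13 Notch pathway genes 7 rose (8 adjusted over the list alone; camera, adjusted p = 0.00712, but adjusted p = 0.192 with an estimated correlation). Of 22 naive pluripotency genes 5 rose and 13 fell (5 and 15 adjusted over the list alone; camera, adjusted p = 0.0154, but adjusted p = 0.148 with an estimated correlation). Of 21 primitive streak and mesendoderm genes 1 rose and 13 fell (1 and 13 adjusted over the list alone; camera, adjusted p = 7.92e-04, but adjusted p = 0.262 with an estimated correlation). Of 20 cell cycle genes 1 rose and 10 fell (1 and 10 adjusted over the list alone; camera, adjusted p = 0.0166, but adjusted p = 0.148 with an estimated correlation). Of 15 p53 target genes 2 rose and 10 fell (2 and 10 adjusted over the list alone; camera, adjusted p = 0.0432, but adjusted p = 0.192 with an estimated correlation), a call lost without doxycycline day 2 replicate 1 (0.0934) or either untreated day 2.5 library (0.0529 and 0.0531). With gene length and GC trends removed, the Notch, cell cycle and p53 calls were lost (camera, adjusted p = 0.0652, 0.0721 and 0.0567). The count of 5 rising naive pluripotency genes was 3 without doxycycline day 2.5 replicate 2. Of 87 small nucleolar RNA and microRNA genes 30 fell and none rose (median log2 -0.87). Without doxycycline 9 of them fell and 1 rose between the days (median -0.58).

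The effect of doxycycline was then compared between the days by an interaction term. Its effect on Kdr was larger at day 2.5 by a log2 of 3.73 ± 0.22 (edgeR, adjusted p = 6.20e-08) and its effect on Gata2 by 6.14 ± 0.29, while for Mixl1, which rose at day 2 and fell at day 2.5, the difference was -3.16 ± 0.14 (adjusted p = 2.27e-09). Part of the Kdr difference came from untreated samples, where Kdr fell from 28.8 to 7.23 CPM between the days. The sample titles do not say when doxycycline was added, so the length of treatment may differ along with the day. For Etv2 itself the difference was 0.47 ± 0.18 (adjusted p = 0.0998), and it passed the test without doxycycline day 2 replicate 1 (adjusted p = 0.00104) and with gene length and GC trends removed (0.62, adjusted p = 0.00200). Of 31 endothelial genes 23 were more positive and 1 more negative (25 and 1 adjusted over the list alone; camera, adjusted p = 3.51e-18, and adjusted p = 0.00411 with an estimated correlation). Of 19 haematopoietic genes 9 were more positive (11 adjusted over the list alone; camera, adjusted p = 1.80e-10, and adjusted p = 0.0487 with an estimated correlation). Among 21 primitive streak and mesendoderm genes 13 were more negative (15 adjusted over the list alone; camera, adjusted p = 7.86e-11, but adjusted p = 0.0700 with an estimated correlation). Of 14 formative epiblast genes 1 was more positive and 7 more negative (2 and 8 adjusted over the list alone; camera, adjusted p = 1.15e-04, but adjusted p = 0.124 with an estimated correlation). Of 13 Notch pathway genes 5 were more positive (5 adjusted over the list alone; camera, adjusted p = 0.0190, but adjusted p = 0.238 with an estimated correlation), a call lost with gene length and GC trends removed (0.0737). Of 5 leukocyte genes 3 were more positive (4 adjusted over the list alone; camera, adjusted p = 0.00824, but adjusted p = 0.116 with an estimated correlation), and the count was 1 without untreated day 2 replicate 1, doxycycline day 2.5 replicate 2 or untreated day 2.5 replicate 2. Of the 13 genes that the study chose for qPCR, 5 were more positive (7 adjusted over the list alone; camera, adjusted p = 3.08e-05, but adjusted p = 0.0700 with an estimated correlation).

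The effect was more positive at day 2.5 for 1000 genes and more negative for 763, and these counts moved with single libraries. Without untreated day 2 replicate 1 or 2 the effect was more positive for 559 or 615 genes and more negative for 278 or 346, and without doxycycline day 2.5 replicate 1 or 2 for 591 or 562 and 439 or 317. Without untreated day 2.5 replicate 2 these counts were 641 and 431, and without doxycycline day 2 replicate 2 they were 2115 and 1954. The more negative genes numbered 1324 without doxycycline day 2 replicate 1 and 495 without untreated day 2.5 replicate 1.

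The comparisons of doxycycline at day 2 and at day 2.5 share no library, but both rest on variation estimated from all 10 libraries. Their lists are therefore not fully independent, and the counts given for independent lists are only a guide. Of the 453 genes that rose at day 2, 331 also rose at day 2.5, where 73.1 would be shared by independent lists, and of the 227 that fell, 134 also fell, against 31.2. Opposite directions were called for 10 and 9 genes, where 62.3 and 36.7 would be shared by independent lists. These overlaps were not taken again with single libraries left out, which moved the day 2 counts. Over all 7 comparisons, the camera calls that held with an estimated correlation were the endothelial list in each comparison except that of the days without doxycycline, the naive pluripotency and p53 lists in that comparison, and the haematopoietic list in the interaction. A call lost in that setting cannot be put down to correlation between genes alone. The endothelial and neuroectoderm lists had estimated correlations of 0.0035 and -0.045, below the preset 0.01. Their camera p nevertheless rose, from 5.47e-20 to 1.76e-04 for endothelial genes with doxycycline at day 2.5. For neuroectoderm genes in Flk1-positive against doxycycline samples it rose from 1.29e-04 to 0.0105.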

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

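Of the tests in this part, the comparison of the doxycycline day 2 libraries with developmental stage was chosen after its uncorrected result had been seen, and the removal of gene length and GC trends was added after the data were seen.

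The effect of doxycycline differed between the days by the interaction test, which drew attention to 1000 genes with a more positive and 763 with a more negative effect at day 2.5. As the time of doxycycline addition is not in the sample titles, day and length of treatment cannot be told apart. A change of the untreated level between the days is also part of each difference. The log2 difference of the effect was 3.73 for Kdr, 9.88 for Fli1, 7.47 for Cdh5, 6.61 for Sox7, 6.14 for Gata2, 3.67 for Tek, 3.20 for Smarca2 and 2.82 for Lmo2. It was -3.36 for Tgm3, -3.18 for Etv4, -3.16 for Mixl1, -2.97 for Fgf17, -2.91 for Frzb, -1.49 for Eomes and -1.28 for Egr1. It was -0.64 for Nodal, a gene chosen for this comparison after its values were seen.

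The interaction rests in part on the doxycycline day 2 libraries, whose log2 differences had an SD of 0.350 over 10813 genes. With trends on gene length and GC content removed the SD was 0.278, against at most 0.211 in the other pairs, so such a trend may account for part of the gap, and the test did not settle whether it accounts for all of it. If replicate 2 were at a later stage, its difference from replicate 1 would follow the change from day 2 to day 2.5 without doxycycline; the correlation across genes, which are not independent replicates, was 0.30 (95% interval over resampled genes 0.28 to 0.32). The bound of 0.3 for that test was set after the uncorrected value had been seen, and the result lies on it, so a difference in stage stays open. With the trends removed, the interaction had 1192 more negative genes in place of 763.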

How the results depend on the processing

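Thinning, the removal of length and GC trends and leaving out small RNA genes were chosen after seeing the data. Of 270 pairs of a named gene and a comparison, 220 had the same direction and side of the threshold in all 23 alternatives run on genes (22 for D7Ertd143e, which has no value with trends removed). Of 55 list calls, 9 did so in the 24 alternatives run on lists, which leave out the fold test and add the estimated correlation and fry. The only change of sign was that of Smarca4 with doxycycline at day 2.5, which was called in no setting: its log2 value was -0.0028 without Flk1-positive replicate 1, -0.0027 without replicate 2, -0.0028 to 0.054 over all libraries left out in turn, and -0.069 with trends removed. Each gene count and each number of list calls moved by over 1.5 times under at least 1 alternative; except where a setting's construction is named, the cause was not tested.

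Counts are given as higher and lower genes. The test against a fold of 1.5, which asks for a larger change, gave 114 and 17 for doxycycline at day 2, 911 and 268 at day 2.5, 807 and 796 for Flk1-positive against doxycycline samples, 2048 and 1423 for Flk1-positive against untreated samples, 32 and 68 between days without doxycycline, 1008 and 664 with it, and 321 and 85 for the interaction. It gives no list test. Fits of the compared groups alone gave 117 and 38 for doxycycline at day 2 and 2299 and 2276 between days without doxycycline; they ended 9 calls of named genes, all for doxycycline at day 2 (adjusted p from 0.0710 to 0.284). The fold test ended 46 such calls, limma-voom 3, thinning 3 and library size scaling 1. Without a filter 437 genes were lower with doxycycline at day 2, and with trends removed 447, and 1192 in the interaction.

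Leaving out 1 library gave 188 to 1035 higher and 58 to 1275 lower genes for doxycycline at day 2, 1566 to 3040 and 1032 to 2945 at day 2.5, 1909 to 3779 and 2095 to 3847 for Flk1-positive against doxycycline samples, 358 to 2266 and 322 to 2536 between days without doxycycline, and 559 to 2115 and 278 to 1954 for the interaction. Of 308 counts of called list members (22 lists, both directions, 7 comparisons), 148 moved by over 1.5 times without at least 1 library: 52 of 164 counts of 3 or more and 96 of 144 counts of 0 to 2.

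In the order of the comparisons in the report, camera called 4, 10, 12, 9, 6, 7 and 7 lists. With an estimated correlation it called 1, 1, 1, 1, 2, 1 and 2. Fry, which tests direction without comparing a list with other genes, called 16 for doxycycline at day 2.5, 18 for Flk1-positive against untreated samples, 11 and 14 between days without and with doxycycline, and 12 for the interaction. In the DESeq2 setting 9 lists were called for doxycycline at day 2, 10 between days without doxycycline and 11 with it, and with trends removed 6 for doxycycline at day 2.5. Without the small RNA genes the extraembryonic endoderm, fibroblast and p53 calls of Flk1-positive against doxycycline samples were lost (adjusted p from 0.0505 to 0.0511).

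Other settings that kept the preset correlation and all libraries ended further camera calls. With doxycycline at day 2.5 the neuroectoderm call was lost in 6 of them (adjusted p from 0.0509 to 0.303), the integrated stress response call in 3 (up to 0.10), the ETS and Notch calls with trends removed (0.0763 and 0.145) and the leukocyte call with DESeq2 (0.0577). For Flk1-positive against doxycycline samples, besides the small RNA setting, the definitive endoderm call was lost in 3 (up to 0.0628), the extraembryonic endoderm call in 6 (up to 0.106), the fibroblast call in 6 (0.0519 to 0.175) and the p53 call in 5 (up to 0.0708). Between days without doxycycline the endothelial call was lost in 2 (0.109 and 0.159) and the extraembryonic endoderm call in 4 (0.0613 to 0.101). Between days with it the p53 call was lost in 2 (0.0567 and 0.0657) and the Notch and cell cycle calls with trends removed (0.0652 and 0.0721). In the interaction the Notch call was lost with trends removed (0.0737) and the leukocyte call with DESeq2 (0.0947).

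Deviations of same-numbered libraries correlated at only -0.034 to 0.098 between groups over all genes tested. This gives no sign of a strong pairing, but it cannot exclude a weaker effect shared by replicate number. Replicate 2 minus replicate 1 was correlated with GC content in the doxycycline day 2 (rank correlation -0.39) and Flk1-positive pairs (-0.5), against -0.038 to 0.046 in the other groups. With the replicate number as a block, the counts were 486 and 254, 2412 and 2089, 3063 and 3190, 4199 and 3947, 1453 and 1641, 3410 and 3422, and 1082 and 859, and no named gene or called list changed its call. Each of these counts was above its value without the block, so an effect shared by replicate number stays open. Other scalings moved the share of higher calls by under 10 percentage points, and library size scaling moved the median of all genes to 0.11 for Flk1-positive against untreated samples. Depth limits what can be said of genes under 0.0824 to 0.164 CPM.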

Other observations

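Chosen after the results were seen were the test of other short genes, both tests of a mix of cells, and the genes named in this part outside the naming rule.

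At day 2.5, 26 genes in doxycycline-treated samples lay outside the range set by untreated and Flk1-positive samples, at least 2-fold above both (20 genes) or below both (6 genes), with both differences called by edgeR. Sox9, a regulator of several progenitor types, had means of 1.34 CPM in untreated, 35.2 CPM in doxycycline-treated and 10.1 CPM in Flk1-positive samples (n = 2 each). The metallothionein gene Mt1 stood at 88.2, 313 and 96.0 CPM and the kinase gene Pdk1 at 135, 345 and 167 CPM. Lhx1, a homeobox gene of the early mesendoderm, lay below both at 37.4, 7.22 and 31.4 CPM, as did Cyp26a1, which encodes a retinoic acid hydroxylase, at 25.5, 10.4 and 59.6 CPM.

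Of 7 noncoding genes looked at after the results were seen, 5 were higher in Flk1-positive than in other doxycycline-treated samples. The log2 difference was 1.71 ± 0.11 for Malat1, 1.90 ± 0.17 for Gas5, 1.74 ± 0.15 for Snhg1, 1.45 ± 0.23 for Snhg12 and 1.31 ± 0.11 for Meg3, with edgeR adjusted p from 3.12e-08 to 2.11e-04. It was -0.05 ± 0.25 for Neat1 (adjusted p = 0.897) and 0.67 ± 0.41 for Kcnq1ot1 (adjusted p = 0.203), which were not called. Malat1 stood at 375 and 451 CPM in the Flk1-positive libraries and at 83.9 to 136 CPM in the other 8.

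Of 87 small nucleolar RNA and microRNA genes, 62 were higher and 1 lower in Flk1-positive than in other doxycycline-treated samples, with a median log2 difference of 2.05. Scaling or depth is argued against by a lowest median of 2.01 over 4 other settings. A trend over all short genes is argued against by a median of -0.0019 over 312 other genes with exons under 1000 bases. These were not matched to the small RNA genes in length, so a bias limited to the shortest RNAs was not tested. For 75 small RNA genes the hosts had a median of 0.46, and the excess over them had a median of 1.38. This argues against host expression as the whole gap over that set, but not as a part of it. Snhg1 and Snhg12, whose symbols name them as small nucleolar RNA hosts, were higher by 1.74 and 1.45, so single hosts came closer. The day 2 libraries, at 384 to 621 CPM for the small RNA genes together, reached the level of the Flk1-positive ones (605 and 589 CPM), and doxycycline day 2.5 was the lowest group (243 and 220 CPM), so the gap may come from a low level in that group as well as from a high level in Flk1-positive samples. Against untreated day 2.5 samples, 53 were higher and 2 lower in Flk1-positive samples (median log2 1.7), and 3 were lower and none higher with doxycycline (median -0.42). Against that baseline the rise in Flk1-positive samples was the larger part. Differences in handling and differences between the cells stay open in either group and were not tested.

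The doxycycline day 2.5 samples might be a mix of cells like the untreated and cells like the Flk1-positive samples in 1 proportion. The share of the way from the first to the second was a median of 0.406 for 490 genes raised at least 4-fold and 0.632 for 261 lowered genes, a difference of 0.23 (0.21 to 0.24 over scalings; 95% interval over resampled genes 0.18 to 0.28), where 0.23 lay above a bound of 0.2, set after the value was seen, and the lower end of the interval lay below it. A second test was therefore added. Under 1 proportion, with no other difference shared by the libraries of a group, the shares would differ between genes only by noise. Shares from replicate 1 and replicate 2 libraries, which have no library in common, had a rank correlation of 0.87 across genes, which argues against noise around 1 proportion. This correlation was taken over raised and lowered genes together, whose median shares differ. The verdict rests on this second test, and the way both were combined was settled after 0.23 was known. The 26 genes outside both groups lay between the bounds set for a test of any mix of these 2 kinds of cells, so that count alone did not decide. A mix of only these 2 kinds in a sample has 1 proportion, however, and places no gene outside both groups if handling was alike. Under that condition, the rank correlation of 0.87 over 751 genes and the 26 genes at least 2-fold outside, with both differences called, argue against such a mix as the whole difference. A difference in handling shared by both libraries of a group would also give reproducible shares and genes outside the range. These values cannot tell it apart, and it was not tested. Mixes with other kinds of cells were not tested.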
